A study of Mus musculus with 96 samples.

How the data were processed

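RNA was measured in 96 libraries from the striatum of 48 mice: an IP and an input library of each mouse, in 6 experiments with 4 treated and 4 control mice each. Per the labels, libraries were made with a stranded total RNA kit after removal of ribosomal RNA and sequenced on a HiSeq 4000. The molecule label, however, reads polyA RNA, and which of these applies is not settled here. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 with STAR and counted with HTSeq, with no versions given. The deposited values are FPKM for 24060 gene entries, of which 21500 were above 0 in at least 1 library. Since FPKM is reads over gene length and library total, each library's values are multiples of a step per gene, and whole read numbers could be recovered from them. At a tolerance of 0.001 reads, 100% of the values were whole, and the recovery was checked on simulated data. The recovered totals ran from 42482787 to 82256165 reads in IP and from 14738821 to 51033642 in input. Each mouse was assigned a sex from Xist and Y-linked genes, and IP and input of the same mouse gave the same sex.

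Tests used limma 3.58.1 in R 4.3.3, with recovery in Python 3.11.15 and numpy 2.4.6 and plots in matplotlib 3.10.9. The test chosen before the data were examined was the quasi-likelihood test of edgeR. limma was used instead of edgeR because the deposited values are FPKM and the recovered reads are a reconstruction from them. FPKM were scaled with TMM factors, 0.1 was added, and log2 values were fitted with a mean-dependent spread (limma-trend). Genes with at least 0.5 FPKM in at least 4 of the libraries of a comparison were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Printed FPKM are the deposited values, and log2 changes come from the scaled values. In each experiment treated mice were compared with controls in IP and in input. The treatment effect was also compared between IP and input with the mouse as a block, IP was compared with input in the 24 control mice, and the CNO effect was compared between rM3Ds and hM3Dq. No sex term was in these fits. The experiments, the groups, the tests other than this replacement, the gene lists and most alternatives were chosen before the data were examined.

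There were 33 gene lists with 528 members (496 distinct genes), all written before the data were examined: markers of astrocytes, medium spiny neurons, striatal interneurons, neurons in general, oligodendrocytes and their precursors, microglia, infiltrating leukocytes, endothelium, mural and ependymal cells, and lists of reactive astrocyte genes and of pathways. Each list was tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with p adjusted over the lists. List members called after adjustment over the list alone are counted beside those called over all genes. Named genes followed a rule. It took the targeted gene, and the 8 largest rises and falls among called genes with a mean of at least 2 FPKM and no overlap between the arms. It added the 5 largest each way among genes enriched in IP, and up to 4 members of each list that was called or had at least 3 changed members. For input and interactions the 5 largest each way were named, for the contrast of the receptors the 8 largest, and for IP against input the 5 largest with a mean of at least 10 FPKM. The minimums had been written for library-scaled counts and were applied to FPKM. Of the genes compared between IP and input Sall1 falls outside this rule and was chosen after its values were seen. Some genes that met this rule are not reported here.

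The fits were tested on simulated data with the spread of these libraries, in which 200 genes changed. In IP 74.6 to 97.0% of genes changed by 2-fold were recovered and 40.3 to 89.6% of genes changed by 1.5-fold. Camera called 0 lists in 6 simulations without change and the raised list in 6 of 6. Arbitrary splits of the real mice, however, called a median of 6.5 to 13 lists per experiment in IP. The simulations therefore do not show how often camera calls lists by chance in these data. Alternatives chosen before the data were examined were RLE scaling, no filter, the replicate number as a block, sex as a covariate, the spread taken over all 48 libraries of a fraction, no mouse block, an estimated correlation, a 2-fold minimum and leaving out each library. Alternatives chosen after seeing the data were the deposited scaling without TMM, a pseudocount of 1 or 0.01, voom on recovered reads, female mice alone in the QA experiment (1 QA mouse, so the spread comes from the vehicle mice alone) and another split of mice as a covariate. A DESeq2 Wald test had been listed and was not run, and voom on recovered reads was used instead of DESeq2. No library was left out of the results.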

Results

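Gene expression was measured in the striatum of 48 mice, in 6 experiments that each set 4 treated mice against 4 controls. Per the labels, an AAV made striatal astrocytes express the ribosomal protein Rpl22 with an HA tag for 3 weeks, and antibodies against the tag then pulled down the ribosomes of these cells with the RNA bound to them (the RiboTag method). Each mouse gave a library of this ribosome-bound RNA (IP) and a library of the cleared tissue lysate before the pull-down (input), so that 96 libraries were sequenced. Their depth ran from 42482787 to 82256165 reads counted in genes in IP and from 14738821 to 51033642 in input. Values are FPKM, given as mean±SD with n = 4 mice per group unless another n is stated. Changes are log2 ratios of treated over control. Steepest and largest changes in an experiment are those among genes that passed the test with a mean of at least 2 FPKM and no overlap between the arms, leaving aside sex-linked genes and provisional names. Behind a gene name, parentheses hold the control value, the treated value and the log2 change. Where a mean lies near or below the 0.1 FPKM added before the log, the size and rank of the change depend on that constant.

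The 6 experiments asked how astrocytes respond to different insults and signals. Quinolinic acid (QA, 30 nM in the labels) is an excitotoxin injected into the striatum 2 weeks before tissue collection to ablate medium spiny neurons, the main neurons of the striatum. Lipopolysaccharide (LPS, 5 mg/kg, 24 h) is a bacterial endotoxin given to provoke inflammation. Kcnj10, which encodes the potassium channel Kir4.1, was targeted in floxed mice with an AAV carrying Cre under an astrocyte promoter, against an AAV carrying TdTomato. Itpr2 encodes the type 2 inositol trisphosphate receptor, through which astrocytes release stored calcium, and mice labelled knockout were compared with wild type. In the remaining experiments astrocytes carried a designer receptor that couples to Gs (rM3Ds) or to Gq (hM3Dq), and its agonist CNO (1 mg/kg) was compared with vehicle. No mice without a receptor were given CNO, so effects of CNO itself are not separated from those of the receptor. CNO was given 2 h before collection with rM3Ds, and the labels give no time for hM3Dq.

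The pull-down enriched astrocyte RNA. In the 24 control mice all 20 astrocyte markers were higher in IP than in input, with a median log2 ratio of 2.62. Among them were the glutamate transporter gene Slc1a2 (168±18.6 in input and 1623±350.0 FPKM in IP, log2 3.48), Kcnj10 (16.3±8.44 in input and 125±43.9 FPKM in IP, log2 3.25) and the transcription factor Sox9 (4.05±0.957 in input and 33.4±8.87 FPKM in IP, log2 3.24). RNA of microglia, endothelium and leukocytes was depleted: 17 of 18 microglia markers, 13 of 13 endothelial markers and 10 of 10 leukocyte markers were lower in IP, with medians of -4.73, -2.70 and -2.43. The complement gene C1qc, which microglia make, went from 102±28.1 in input to 1.91±0.516 FPKM in IP (log2 -5.42), and the exception was Sall1, a transcription factor listed as a microglia marker, which was higher in IP. Of 20 medium spiny neuron markers 19 were lower in IP (median -1.08), whereas 10 of 12 striatal interneuron markers were higher (median 1.75), led by Nos1 (9.03±0.764 in input and 73.4±15.6 FPKM in IP, log2 3.22), the neuronal nitric oxide synthase. All 9 markers of ependymal cells, the ciliated cells that line the ventricles, were higher as well (median 1.76). Among the other markers 5 of 12 for oligodendrocytes were higher and 3 lower, 7 of 9 for their precursors were higher and 1 lower, 4 of 9 for mural cells were higher and 5 lower, and 6 of 14 pan-neuronal markers were higher and 8 lower. Over all genes 6843 were higher and 6935 lower in IP of 15566 tested (limma, adjusted p under 0.05, n = 24). Without TMM scaling these numbers were 4900 and 9051, so the direction of genes near a ratio of 1 depends on the scaling.

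**Figure D1:**
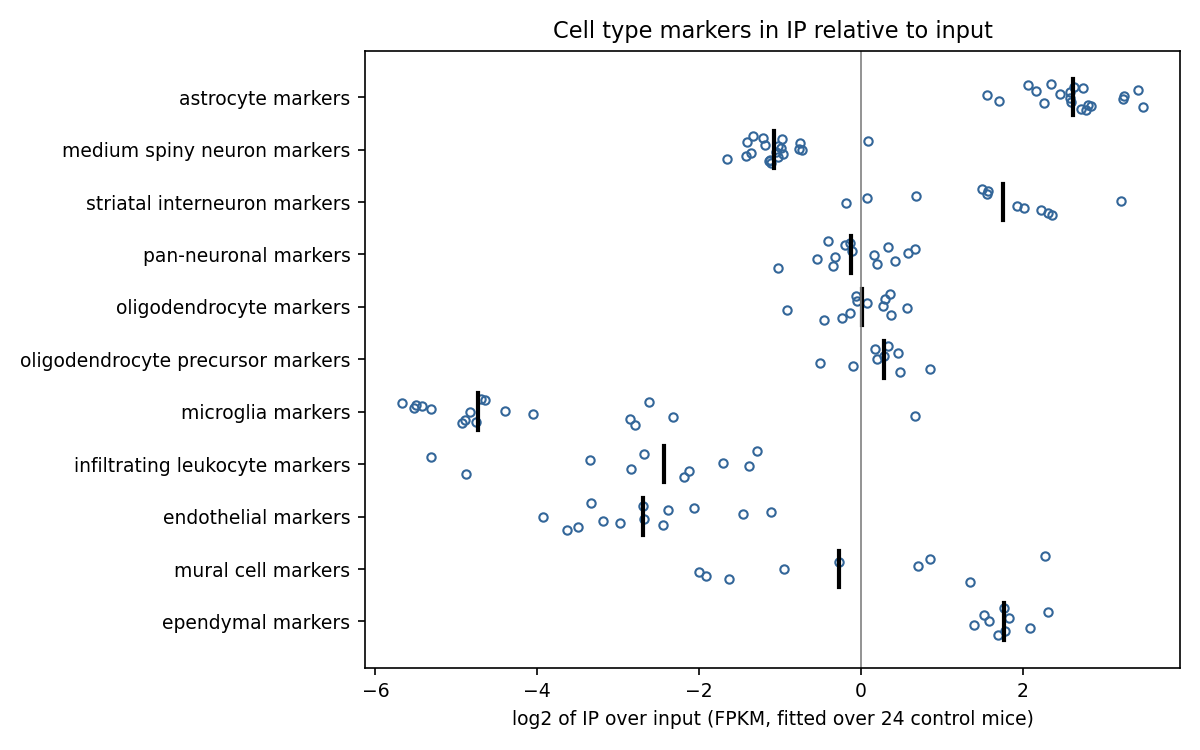
Log2 ratio of IP over input for the markers of each cell type in the 24 control mice, 1 point per gene. Astrocyte markers centre on 2.62 and striatal interneuron markers on 1.75, whereas microglia markers centre on -4.73.

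The targeted genes were examined in every sample. Kcnj10 lay at 142 to 164 FPKM in the 4 TdTomato IP libraries and at 27.9 to 36.1 in the 4 Cre IP libraries, a fall from 149.7±10.1 to 31.4±3.45 FPKM (log2 change -2.21 ± 0.07 SE, limma adjusted p = 1.9e-07). In input Kcnj10 was 23.4 ± 2.24 with TdTomato and 13.3 ± 3.43 with Cre, a difference that did not pass the test (log2 -0.81, limma adjusted p = 0.098). Itpr2 was not lower in the libraries labelled knockout. Its IP values were 9.92 to 13.7 FPKM in the 4 wild-type libraries and 10.4 to 14.5 in the 4 labelled knockout (log2 0.07 ± 0.13 SE, limma adjusted p = 0.98), and its input values were 3.14 ± 0.211 and 3.66 ± 0.446. A gene-level value includes reads from outside the deleted part of a gene, so where a deletion leaves most of the transcript it checks nothing. Chrm3, the gene of the muscarinic receptor from which both designer receptors derive, was 214 ± 25.5 and 202 ± 21.3 FPKM in vehicle and CNO IP with rM3Ds and 91.8 ± 16.6 and 94.2 ± 30.4 with hM3Dq, against group means of 1.74 to 4.47 in IP of the other 4 experiments. The high values thus went with the receptor experiments, in vehicle and CNO alike. Gene-level values do not tell reads of the rat- or human-derived receptor from reads of the mouse gene.

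The number of genes that changed in IP ranged from 0 to 10238 between the experiments. QA changed 10238 of 13824 genes tested, CNO with hM3Dq 6224 of 13563, LPS 5016 of 13641, Kcnj10 deletion 3999 of 13537 and CNO with rM3Ds 620 of 13535. Between the libraries labelled Itpr2 knockout, in which Itpr2 was not lower, and wild type 0 of 13359 passed (limma, adjusted p under 0.05; for Itpr2 788 at an unadjusted p under 0.05 and 0 by voom). At least 2-fold changes numbered 1337 higher and 1524 lower after QA, 687 and 271 after LPS, 16 and 251 with Kcnj10 deletion, 172 and 17 with rM3Ds, and 704 and 340 with hM3Dq. Without TMM scaling the median log2 change of all genes shifted by -0.14 in LPS IP and by 0.14 in QA input, and changes there are relative to that. Other splits of genes into higher and lower in IP also turned on this scaling. With TMM they were 1910 higher and 2089 lower for Kcnj10 deletion, 2611 and 2405 for LPS and 3648 and 2576 for hM3Dq. Without TMM they were 1249 higher and 2700 lower for Kcnj10 deletion, 1833 and 4022 for LPS and 2930 and 3298 for hM3Dq. For gene lists the number that camera called at the preset correlation was matched or passed in 4 to 16 of 35 splits of the same mice, so list p values below describe the lists and do not exclude chance.

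At 2 weeks after QA, neuronal RNA was low and glial reactive genes were high in the astrocyte pull-down. All 13 pan-reactive astrocyte genes rose (13 adjusted over the list alone), among them the intermediate filament gene Vim (162±13.2 to 1884±458, 3.46), the hyaluronan receptor Cd44 (10.9±0.397 to 64.6±6.11, 2.51) and the oncostatin M receptor Osmr (10.96±0.433 to 65.5±5.44, 2.52). Of the A1 list of reactive genes, defined for inflammation, 8 of 11 rose and 2 fell (8 and 2 adjusted over the list alone), and of the A2 list, defined for ischemia, 9 of 11 rose (9 adjusted over the list alone). They included Gbp2 (179±23.2 to 1100.1±429, 2.48) and Tgm1 (8.66±1.22 to 59.5±9.24, 2.72). The steepest rises at a mean of at least 2 FPKM were in the serine protease gene Klk8 (0.945±0.421 to 48.1±22.0, 5.47), the annexin Anxa3 (2.10±0.427 to 45.3±7.15, 4.33) and the insulin-like growth factor binding proteins Igfbp3 (5.24±0.353 to 89.8±17.8, 4.01) and Igfbp2 (29.6±4.56 to 489.6±70.7, 4.00). Next came galectin-1, Lgals1 (18.5±0.793 to 248±44.2, 3.67), Syt15 (0.875±0.0612 to 12.9±2.70, 3.67), S100a11 (1.01±0.390 to 13.6±3.12, 3.62) and the metalloproteinase Mmp19 (0.639±0.0858 to 8.64±1.13, 3.52). Camera gave adjusted p = 4.6e-06 for the pan-reactive list, and adjusted p = 0.36 with an estimated correlation. For the A1 and A2 lists it gave adjusted p = 0.035 and 1.2e-04, and adjusted p = 0.44 and 0.45 with an estimated correlation.

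Immune pathways rose together with these genes. Of the interferon response list 21 of 22 genes rose (21 adjusted over the list alone), such as Parp14 (7.92±1.47 to 36.0±8.86, 2.11). Of the NF-kappa-B and acute-phase list 15 of 16 rose and 1 fell (15 and 1 adjusted over the list alone), such as the iron-binding protein Lcn2 (5.50±1.39 to 54.6±11.7, 3.26) and the cytokine signalling inhibitor Socs3 (3.35±0.447 to 23.4±6.86, 2.70). All 14 genes of MHC class I antigen presentation rose (14 adjusted over the list alone), as did 13 of 14 complement genes with 1 lower (13 and 1 adjusted over the list alone), such as C4b (202±12.9 to 374±32.1, 0.84). By camera the result was adjusted p of 1.9e-05, 3.4e-05, 0.0019 and 6.6e-04 for these 4 lists, and adjusted p = 0.49, 0.49, 0.51 and 0.49 with an estimated correlation. Microglia markers moved the same way, 18 of 18 higher with a median of 1.77, for example C1qb (2.89±0.196 to 13.4±3.30, 2.09). So did oligodendrocyte markers, 12 of 12 higher with a median of 1.00, for example Mbp (264±12.9 to 685±93.6, 1.32), and ependymal markers, 9 of 9 higher with a median of 0.91. Of 3 leukocyte markers tested, 2 rose and 1, Cd4 (9.62±0.507 to 1.64±0.732, -2.65), fell. Proliferation genes rose in 10 of 11 cases (10 adjusted over the list alone), such as Top2a (0.452±0.133 to 4.58±1.95, 2.98), with adjusted p = 0.0049 by camera and adjusted p = 0.49 with an estimated correlation.

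Neuronal RNA in the pull-down fell. All 20 medium spiny neuron markers were lower (20 adjusted over the list alone, median -2.39), including the enkephalin precursor Penk (899±44.4 to 172±25.1, -2.44) and the dopamine receptor Drd2 (46.9±1.85 to 9.18±1.51, -2.40). So were all 12 interneuron markers (12 adjusted over the list alone, median -1.83), including the acetylcholine-synthesizing enzyme Chat (41.2±2.47 to 9.94±0.882, -2.09). Among the steepest falls were those of Coch (37.7±2.40 to 3.15±1.18, -3.67), the sodium channel subunit Scn4b (167±4.32 to 19.1±6.84, -3.24), the calcium sensor Hpca (381±9.78 to 49.4±18.7, -3.08), Gpr139 (5.63±0.419 to 0.624±0.151, -3.05), Rgs4 (246±6.35 to 32.5±9.81, -3.01), Acvrl1 (9.07±0.0742 to 1.10±0.215, -2.99) and Rasgrp2 (60.8±2.71 to 8.33±2.61, -2.95). Tested with camera, the result was adjusted p = 3.2e-08 for the medium spiny neuron list and adjusted p = 3.4e-05 for the interneuron list, and adjusted p = 0.49 and 0.21 with an estimated correlation. Of the astrocyte markers 12 of 20 rose and 3 fell (12 and 3 adjusted over the list alone), with the water channel Aqp4 (258±9.27 to 727±23.7, 1.45) and Kcnj10 (88.1±4.51 to 177±11.7, 0.96) among the risers (adjusted p = 0.009, and adjusted p = 0.49 with an estimated correlation). Cholesterol biosynthesis fell in 16 of 20 genes (16 adjusted over the list alone), with adjusted p = 8.1e-04 by camera and adjusted p = 0.49 with an estimated correlation, whereas the cholesterol exporter Abca1 (31.5±3.02 to 149±8.27, 2.19) rose. The QA arm held 1 female and 3 males and the vehicle arm 4 females, so QA and sex are hardly separable here. With sex as a covariate 7828 genes changed, a count that rests on the 1 female QA mouse, and the named genes Sox10, Olig1, Cldn5, Dynlrb2 and Psme2 lost their call.

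QA also changed the whole tissue, with 5066 genes higher and 5852 lower in input of 14831 tested. Without TMM scaling the input counts were 6183 higher and 4374 lower. The largest rises there were in genes of phagocytes, Gpnmb (1.37±0.251 to 79.6±19.3, 5.61), Apoc2 (0.270±0.0872 to 9.38±3.33, 4.53), Ms4a7 (0.441±0.156 to 12.4±4.12, 4.39), Lilrb4 (1.04±0.457 to 25.3±8.94, 4.36) and Cst7 (12.3±2.44 to 286±114, 4.29). The largest falls were in Gpx6 (4.73±0.567 to 0.449±0.178, -3.33), Coch (52.3±2.39 to 8.46±2.49, -2.81), the microRNA gene Mir382 (6.20±0.973 to 0.996±0.311, -2.69), Gpr139 (12.5±2.05 to 2.18±0.634, -2.64) and the cannabinoid receptor Cnr1 (134±1.87 to 30.0±5.60, -2.32). The QA effect differed between IP and input for 7187 genes, of which 1901 changed more upward in IP and 5286 more downward (limma interaction, adjusted p under 0.05). Anxa3 (4.33 in IP and 2.29 in input), Klk8 (5.47 in IP and 3.57 in input) and the ligand of the Kit receptor Kitl (1.57 in IP and -0.29 in input) rose more in IP. By contrast Gpnmb (2.16 in IP and 5.61 in input) and Spp1 (0.79 in IP and 4.13 in input) rose more in input. By RLE scaling the interaction counts were 2854 and 4205.

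LPS raised reactive and acute-phase genes in the astrocyte pull-down within 24 h. Lipocalin-2 (Lcn2) rose from 4.46±3.31 to 579.1±233 FPKM (log2 change 7.28 ± 0.46 SE, limma adjusted p = 1.0e-04). The chemokine Ccl2 (7.11±5.05 to 498±373, 5.69), the pentraxin Ptx3 (2.56±1.72 to 101±64.0, 5.16), Tnfaip2 (3.69±1.56 to 154±98.9, 5.12), Steap4 (0.193±0.122 to 14.7±8.79, 5.66), the sphingosine kinase Sphk1 (0.159±0.0595 to 19.2±12.9, 5.85), Serpina3m (0.0231±0.0235 to 9.19±3.09, 6.28) and the fibrinogen chain Fga (0.0128±0.00729 to 12.5±7.99, 6.25) completed the 8 steepest rises among genes above the expression minimum for naming, of which Fga lost its call by voom on recovered reads (adjusted p = 0.083). The steepest falls were in 2 Notch pathway genes, Hes5 (20.4±6.05 to 1.58±2.27, -4.28) and Nrarp (24.7±2.74 to 4.20±6.82, -3.67), the precursor cell receptor Gpr17 (8.40±0.468 to 1.31±2.25, -3.80), Ak4 (11.6±1.42 to 2.70±2.08, -2.17), Shisa2 (4.11±0.738 to 0.892±0.691, -2.15), Fam13c (14.5±0.981 to 4.05±3.599, -1.98), Kctd21 (6.32±0.246 to 1.99±2.16, -1.95) and Fam198a (7.07±0.671 to 2.01±1.66, -1.91). Kctd21 lost its call without LPS replicate 3 or vehicle replicate 2 (largest adjusted p = 0.057). Among the rises, Serpina3m, Fga and Sphk1 had control means near or below the 0.1 FPKM added, so their size and rank are uncertain. Over the alternatives in which they were tested, their log2 changes ran from 3.33 to 8.78, from 3.37 to 9.17 and from 3.79 to 6.55. LPS replicate 2 stood apart from the other LPS mice. On the axis from the vehicle mean to the LPS mean over the changed genes it lay 40.0% of the way in IP and 46.5% in input, against 115 to 126% for the other 3 LPS IP libraries, and it is part of every LPS mean and SD given here.

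All 13 pan-reactive genes rose after LPS (13 adjusted over the list alone), for example Serpina3n (58.9±27.9 to 684±194, 3.74) and the small heat shock protein Hspb1 (4.46±1.33 to 102±45.1, 4.54). So did 10 of 11 A1 genes, such as Amigo2 (7.01±0.332 to 16.4±1.86, 1.35), and 9 of 11 A2 genes, such as Cd109 (2.47±0.855 to 15.98±4.00, 2.82) (10 and 9 adjusted over the list alone). All 17 NF-kappa-B and acute-phase genes rose (17 adjusted over the list alone), with the chemokine Cxcl1 (0.552±0.181 to 18.6±12.7, 4.69) and Bcl3 (1.27±0.578 to 7.59±2.49, 2.65) as examples. So did 16 of 22 interferon response genes (17 adjusted over the list alone), such as Mx1 (2.61±2.16 to 31.3±21.3, 3.52). Of MHC class I presentation genes 13 of 14 rose (14 adjusted over the list alone), such as H2-K1 (246±59.4 to 537.4±63.0, 1.30), and of complement genes 10 of 12 (10 adjusted over the list alone), such as C3 (6.26±2.60 to 31.7±10.4, 2.51). All 16 genes of the glucocorticoid response rose (16 adjusted over the list alone), including Fkbp5 (7.59±0.580 to 40.9±4.61, 2.55), Plin4 (0.832±0.217 to 20.3±7.28, 4.56) and the metallothionein Mt1 (749±91.6 to 3964±486, 2.55). Camera gave adjusted p of 5.6e-10, 2.9e-06, 1.5e-05, 5.1e-10, 3.8e-05, 7.5e-08, 1.1e-05 and 2.6e-10 for these 8 lists in that order, and adjusted p = 0.31, 0.31, 0.43, 0.41, 0.62, 0.49, 0.41 and 0.31 with an estimated correlation. H2-K1 belongs to a family of near-identical genes that can share reads, so its value is uncertain.

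Cell type markers changed in part. Of 20 medium spiny neuron markers 11 fell after LPS (11 adjusted over the list alone), such as Drd2 (42.5±2.27 to 29.5±3.20, -0.39), with adjusted p = 0.012 by camera and adjusted p = 0.68 with an estimated correlation. Of 12 microglia markers 4 rose (4 rose and 2 fell adjusted over the list alone), such as C1qa (2.01±0.385 to 3.45±0.358, 0.90). Of 12 oligodendrocyte markers 5 rose and 2 fell, such as Ugt8a (22.95±5.90 to 7.03±2.97, -1.60), and of 9 oligodendrocyte precursor markers 3 fell, Gpr17 among them. Of 20 astrocyte markers 6 rose and 2 fell, with the gap junction gene Gjb6 (53.8±5.72 to 101±5.69, 1.05) as an example. For the microglia, oligodendrocyte, precursor and astrocyte lists camera adjusted p was 0.50, 0.23, 0.073 and 0.049, and 0.72, 0.72, 0.65 and 0.65 with an estimated correlation. The count of changed genes depended on single mice. Leaving out LPS replicate 2 raised it to 8256, and leaving out LPS replicate 1, 3 or 4 or vehicle replicate 1, 2, 3 or 4 lowered it to 3153, 2155, 2645, 2594, 2496, 2477 and 2856.

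In input LPS changed 2264 genes upward and 2238 downward of 14511 tested. Lcn2 (1.34±0.490 to 343±48.4, 8.02), the serum amyloid gene Saa3 (2.22±1.14 to 479.5±213, 7.78), the colony-stimulating factor Csf3 (0.0139±0.0161 to 21.1±14.5, 6.66), Marco (0.00930±0.0108 to 10.02±3.55, 6.50) and the chemokine Ccl3 (0.976±0.307 to 108±88.2, 5.95) rose most. The microglial receptors Gpr34 (9.29±0.333 to 0.396±0.321, -4.39), P2ry13 (6.43±0.378 to 1.11±1.36, -2.92) and P2ry12 (17.9±1.74 to 2.34±1.02, -2.91) fell most, with Hes5 (11.98±2.34 to 1.79±2.42, -3.41) and Gpr17 (10.04±0.773 to 2.89±4.17, -2.62). The LPS effect differed between IP and input for 1308 genes, 758 more upward and 550 more downward in IP. Olfml3 (2.34 in IP and -1.30 in input) and the chemokine Ccl8 (2.73 in IP and -0.14 in input) rose more in IP. P2ry12 fell in input only by these tests (log2 -0.05 in IP and -2.91 in input, limma interaction adjusted p = 0.0023). S100a8, S100a9, Il1rn and Marco, genes of infiltrating and phagocytic cells that were too low for testing in IP, rose in input and differed by the interaction. Without LPS replicates 1, 2, 3 and 4 in turn the input count was 2577, 8623, 1757 and 2187 and the interaction count 521, 4823, 296 and 469. Without vehicle replicates 1, 2, 3 and 4 in turn they were 2012, 1969, 1864 and 2367 for input and 395, 330, 379 and 542 for the interaction. Without the mouse as a block the interaction count was 168, and without TMM scaling it was 634 higher and 1091 lower.

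Reactive and immune genes were lower with Cre than with TdTomato in the Kcnj10 experiment. No group without a virus of this kind was measured, so a fall with Cre and a rise with TdTomato are not separated by these values. Of 88 genes in 7 reactive and immune lists 77 were higher in IP than in input of control mice, and 74 of these 77 fell by more than the loss of all RNA carried over from microglia would allow. At the upper limit for carry-over from any cells 57 of 77 did. All 12 pan-reactive genes tested fell with Cre (12 adjusted over the list alone, median -1.59), among them Vim (172±14.6 to 54.2±8.67, -1.63), Cd44 (15.98±2.36 to 4.50±0.349, -1.76) and Serpina3n (55.2±9.97 to 18.2±3.14, -1.56). Of the A1 list 7 of 11 fell and 1 rose (8 and 1 adjusted over the list alone), such as Gbp2 (218±77.5 to 36.9±12.8, -2.53), and of the A2 list 6 of 8 fell (6 adjusted over the list alone), such as Tgm1 (5.09±1.22 to 0.778±0.346, -2.58). Of interferon response genes 20 of 22 fell (22 adjusted over the list alone), such as Ifit3 (122±20.3 to 47.8±18.1, -1.38). So did 14 of 15 NF-kappa-B genes (14 adjusted over the list alone), such as Cebpd (12.7±0.997 to 3.72±0.679, -1.72). Of MHC class I presentation genes 13 of 14 fell (14 adjusted over the list alone), such as the peptide transporter Tap1 (25.6±6.80 to 9.91±2.505, -1.32), and of complement genes 9 of 11 (9 fell and 1 rose adjusted over the list alone), such as C1s1 (5.41±1.66 to 0.922±0.361, -2.40). By camera the result was adjusted p of 6.2e-11, 0.0013, 2.2e-04, 7.4e-09, 4.0e-13, 4.5e-07 and 5.0e-05 for these 7 lists, and adjusted p = 0.26, 0.48, 0.26, 0.50, 0.19, 0.48 and 0.34 with an estimated correlation.

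The steepest falls with Cre were in the chemokines Ccl2 (10.7±2.53 to 0.985±0.904, -3.55) and Cxcl10 (69.6±16.5 to 8.16±4.89, -3.16), Anxa3 (8.91±1.31 to 0.727±0.273, -3.45), the growth factor Igf2 (5.78±0.325 to 0.512±0.140, -3.26), Gdf15 (4.96±1.01 to 0.536±0.340, -3.11), the adhesion molecule Icam1 (33.2±2.39 to 3.72±0.692, -3.10), Ifi202b (6.45±1.87 to 0.710±0.322, -3.02) and Sgca (6.73±0.448 to 0.745±0.191, -3.002). The rises were smaller, led by the lysyl oxidase relative Loxl1 (1.498±0.284 to 3.51±0.231, 1.23), the small RNA genes AF357426 (4.27±2.13 to 8.65±1.08, 1.16) and DQ267100 (2.04±0.244 to 4.80±2.59, 1.11), the histone gene Hist2h2be (2.92±0.117 to 5.49±0.651, 0.92) and Btbd17 (16.6±1.43 to 29.1±3.14, 0.85). They included proline dehydrogenase, Prodh (31.8±2.84 to 55.5±6.14, 0.84), Fam163a (6.18±0.284 to 10.7±0.501, 0.82) and apelin, Apln (24.6±2.15 to 42.2±4.38, 0.82). Values of such small RNA genes and of histone genes, which share or overlap other transcripts, are uncertain, and the labels differ on whether RNA was polyA RNA or depleted of ribosomal RNA. AF357426 and DQ267100 lost their call when the spread was taken over all 48 IP libraries. Of the astrocyte markers 4 of 20 rose and 3, Kcnj10 included, fell (4 and 3 adjusted over the list alone), with Slc1a2 (1360.2±83.4 to 1667±43.3, 0.34) and Aldh1l1 (84.7±5.97 to 118±10.4, 0.52) among the risers, a median of 0.05 and a mean of -0.04.

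Medium spiny neuron markers rose with Cre and most oligodendrocyte markers fell. Of 20 medium spiny neuron markers 19 rose (20 adjusted over the list alone, median 0.26), such as Drd1a (52.6±1.12 to 68.4±2.25, 0.42). By contrast 11 of 12 oligodendrocyte markers fell (12 adjusted over the list alone, median -0.53), such as Mag (117±15.5 to 70.4±4.26, -0.68), and 5 of 13 microglia markers fell (5 adjusted over the list alone, median -0.45), such as C1qa (3.81±0.472 to 2.06±0.339, -0.82). Of 8 mural markers 5 fell and 1 rose, and of 8 endothelial markers 3 fell. Tested with camera, the result was adjusted p of 2.9e-11, 4.7e-06, 0.011, 0.026 and 0.038 for these 5 lists, and adjusted p = 0.19, 0.48, 0.48, 0.37 and 0.55 with an estimated correlation. Other neuronal markers did not share one direction. Of 12 interneuron markers 3 fell and 1 rose (3 and 1 adjusted over the list alone), with Nos1 (81.5±5.08 to 65.7±1.08, -0.27) and Npy (547±21.0 to 451±20.5, -0.24) among the falls, which both lost their call with the spread taken over all 48 IP libraries (adjusted p = 0.20 and 0.19), and of 14 pan-neuronal markers 5 rose (6 adjusted over the list alone). These 2 lists did not pass by camera (adjusted p = 0.16 and 0.052, and adjusted p = 0.61 and 0.74 with an estimated correlation). Calcium signalling genes rose in 9 of 19 cases (11 adjusted over the list alone), such as the phospholipase Plcb1 (94.5±0.653 to 119.7±2.72, 0.38). Cholesterol biosynthesis rose in 7 of 20 (9 adjusted over the list alone), and camera gave these 2 lists adjusted p = 1.0e-04 and 0.0011, and adjusted p = 0.26 and 0.55 with an estimated correlation. With the spread taken over all 48 IP libraries 1631 genes passed, 818 higher and 813 lower.

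In input 49 of 14160 genes passed with Cre, 2 higher and 47 lower. Dio2 (13.8±1.30 to 20.3±0.8289, 0.60) and Sfxn5 (46.1±2.29 to 56.6±3.25, 0.33) rose, and Cxcl10 (15.8±3.87 to 2.40±1.19, -2.74), Cst7 (8.52±5.33 to 1.498±0.377, -2.26), Gbp5 (4.11±1.09 to 1.09±0.634, -1.89), Icam1 (6.86±0.931 to 1.86±0.604, -1.83) and Gbp2 (35.5±12.6 to 9.62±2.70, -1.82) fell most. The Cre effect differed between IP and input for 359 genes, 80 more upward and 279 more downward in IP. Anxa3 (-3.45 in IP and -0.57 in input), Igf2 (-3.26 in IP and -0.48 in input) and Cxcl9 (-2.83 in IP and -1.29 in input) fell more in IP. The input libraries of Cre replicates 1 to 4 and of TdTomato replicate 4 had few genes with a single read, 15.8 to 22.9% of those with 1 to 5 reads against 30.3 to 32.3% in the other 3. This difference largely goes along with the arm. It may be a sign of low library complexity, which was not measured. The input count was 1, 4, 4 and 26 without TdTomato replicates 3, 1, 4 and 2, and 19, 15 and 86 without Cre replicates 1, 3 and 4. The interaction count was 127, 133, 203 and 132 without TdTomato replicates 1, 2, 3 and 4 and 231, 207 and 187 without Cre replicates 1, 2 and 3.

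No gene passed between the libraries labelled Itpr2 knockout and wild type in IP. The wild-type group held 3 females and 1 male and the group labelled knockout 4 females. Of 13359 genes tested by limma 0 passed, 788 had an unadjusted p under 0.05, the smallest adjusted p was 0.37, and voom on recovered reads also gave 0. In simulated data with the spread of these libraries, in which 200 genes changed, 88.1% of genes changed by 2-fold and 56.7% of genes changed by 1.5-fold were recovered. With fewer changed genes the adjusted cut-off is stricter, so this does not show that a lone 2-fold change would be found. Interferon response genes were lower in the libraries labelled knockout as a group, with a median of -0.74: 0 of 22 passed over all genes and 19 passed adjusted over the list alone (adjusted p = 3.5e-26, and adjusted p = 0.13 with an estimated correlation). MHC class I presentation genes had a median of -0.81, with 0 of 14 and 9 adjusted over the list alone (adjusted p = 1.9e-16, and adjusted p = 0.13 with an estimated correlation). A1 reactive genes had a median of -0.82, with 0 of 11 and 5 adjusted over the list alone (adjusted p = 4.1e-08, and adjusted p = 0.13 with an estimated correlation). Of cell type markers no gene passed either. Camera called pan-neuronal markers higher (median 0.11) and oligodendrocyte precursor and ependymal markers lower (medians -0.13 and -0.31), with adjusted p of 0.0048, 0.013 and 0.017, and adjusted p = 0.67, 0.13 and 0.67 with an estimated correlation. Microglia markers (median -0.05) and oligodendrocyte markers (median -0.21) were not called as lists, with adjusted p = 0.66 and 0.058. Camera also called the pan-reactive, A2, NF-kappa-B, complement and unfolded protein lists lower, with adjusted p of 7.1e-05, 0.0038, 0.0020, 3.4e-06 and 0.024, and adjusted p = 0.13, 0.54, 0.25, 0.13 and 0.67 with an estimated correlation. Immediate early and cholesterol biosynthesis genes were called higher as lists, with adjusted p of 0.017 and 0.0041, and adjusted p = 0.67 for both with an estimated correlation. Of 35 splits of these mice 5, the real one included, called as many lists, so no direction here can be assigned to loss of Itpr2. The gene-level value of Itpr2, which was not lower, does not tell whether the gene was lost.

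In input 1 gene, Mir7036b, passed, a fall from 4.62±0.615 to 0.924±0.401 FPKM (log2 change -2.25 ± 0.24 SE, limma adjusted p = 0.037), and 1267 genes had an unadjusted p under 0.05. A microRNA gene is short and can take reads from its host transcript, so this value is uncertain, and the call was lost in voom on recovered reads, which gave 0 genes. The difference between IP and input was tested for 14482 genes and 0 passed by limma (716 at an unadjusted p under 0.05, and 0 by voom). The IP count was 9 without wild-type replicate 3 and 1 without wild-type replicate 1 or replicate 1 or 4 of the knockout label, and with the spread taken over all 48 IP libraries it was 29. The input count was 2 without knockout-label replicate 1 or wild-type replicate 3, 3 without knockout-label replicate 2, and 0 without knockout-label replicate 3 or 4 or wild-type replicate 2 or 4, and the interaction count was 1 without knockout-label replicate 4.

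In mice with the Gs-coupled receptor rM3Ds a compact set of early response genes was higher in the astrocyte pull-down 2 h after CNO. Of 21 immediate early genes 14 rose (16 adjusted over the list alone, median 2.02), among them the transcription factor Fos (12.1±1.64 to 177±29.5, 3.87), Klf4 (0.447±0.0334 to 29.1±1.69, 5.75) and Fosl2 (3.76±0.646 to 64.5±8.34, 4.08). Of 21 targets of cAMP and CREB 15 rose (16 adjusted over the list alone, median 1.33), among them the small GTPase Gem (4.09±0.202 to 146±13.3, 5.13), the nuclear receptors Nr4a1 (5.69±0.783 to 87.0±6.47, 3.93) and Nr4a3 (2.77±0.635 to 43.0±4.93, 3.94) and the kinase Sik1 (4.09±0.251 to 17.7±2.09, 2.09). These 2 lists kept their calls, with camera adjusted p of 1.2e-33 and 1.0e-35 and adjusted p = 0.021 and 0.0075 with an estimated correlation. The other steep rises were in the cytokines Il11 (0.172±0.0649 to 6.96±2.03, 4.69) and Il6 (0.2903±0.104 to 7.66±1.59, 4.34), the chemokine Cxcl1 (0.340±0.0876 to 8.56±1.87, 4.31), Maff (2.47±0.518 to 52.2±6.30, 4.37) and thrombospondin-1, Thbs1 (0.333±0.0567 to 7.84±2.52, 4.16). The steepest falls were in Hes5 (9.93±2.28 to 1.18±0.642, -3.09) and Lfng (26.2±7.92 to 6.11±1.89, -2.08), both of the Notch pathway, the ephrin receptor Ephb3 (4.85±0.530 to 1.87±0.335, -1.32) and Txnip (15.03±5.62 to 5.91±0.432, -1.26). They were followed by the platelet-derived growth factor receptor Pdgfrb (8.11±0.623 to 3.59±0.546, -1.15), Plekho2 (8.99±1.07 to 4.25±0.316, -1.05), Stk17b (11.95±1.02 to 5.71±0.228, -1.04) and Fam181b (41.5±4.62 to 20.7±2.82, -0.99).

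Cholesterol biosynthesis rose with rM3Ds in 9 of 20 genes (11 adjusted over the list alone), such as Pmvk (31.5±1.31 to 87.8±16.4, 1.47), with adjusted p = 8.8e-10 by camera and adjusted p = 0.43 with an estimated correlation. Of 16 NF-kappa-B and acute-phase genes 7 rose (9 adjusted over the list alone), such as Socs3 (2.78±0.662 to 17.0±5.35, 2.56). Of 10 A2 reactive genes 5 rose (5 adjusted over the list alone), such as the cyclooxygenase Ptgs2 (0.440±0.190 to 3.51±0.367, 2.82), with camera adjusted p of 1.3e-08 and 5.1e-05 and adjusted p = 0.17 and 0.54 with an estimated correlation. Of the other reactive genes 1 of 12 pan-reactive and 0 of 11 A1 genes passed, and of interferon response genes 1 of 22 passed. Glucocorticoid response genes rose in 2 of 16 cases and unfolded protein genes in 2 of 17 (6 and 5 adjusted over the list alone), and 2 of 9 genes of the Sonic hedgehog pathway fell (2 adjusted over the list alone). Camera called these 3 lists with adjusted p of 5.1e-05, 0.0017 and 0.0039, and adjusted p = 0.43 for each with an estimated correlation. Among cell type markers 0 of 20 for medium spiny neurons, 0 of 12 for interneurons and 0 of 9 for ependymal cells passed by limma, and of 20 astrocyte markers 1 rose and 1 fell. As lists the medium spiny neuron markers were called higher (median 0.11), and the astrocyte markers (median -0.14) and the potassium, glutamate and GABA homeostasis genes (median -0.09) lower, with camera adjusted p of 0.014, 0.014 and 0.032, and adjusted p = 0.71 for each with an estimated correlation. Of microglia markers 1 of 14 rose and 1 fell. Over the whole fit 1675 genes had an unadjusted p under 0.05, and voom on recovered reads called 644. The regulator of glycogen synthesis Ppp1r3g (13.8±3.67 to 51.2±5.04, 1.93) rose, and the transcription factor Sox9 (28.5±2.94 to 15.5±1.27, -0.86) fell.

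The rM3Ds counts carry a limit. Another way of splitting the 8 mice, vehicle replicates 1 and 4 with CNO replicates 3 and 4 against the rest, called 2185 genes, and with that split as a covariate 960 genes changed with CNO, 631 higher and 329 lower. The count was 413 without CNO replicate 4. In input 83 genes rose and 3 fell of 14387 tested. The highest were Gem (1.59±0.361 to 35.2±2.87, 4.39), Maff (1.12±0.455 to 11.9±2.27, 3.34), the protease Adamts1 (2.77±0.353 to 23.7±2.08, 3.05), Cyr61 (2.78±0.465 to 22.5±2.501, 2.97) and Fos (6.81±2.45 to 49.9±4.61, 2.91), and Lfng (8.53±1.92 to 4.71±0.257, -0.83) and Fam181b (10.5±0.965 to 6.94±0.422, -0.59) fell. The CNO effect differed between IP and input for 306 genes, 240 more upward and 66 more downward in IP. Nr4a3 (3.94 in IP and 0.98 in input), Klf4 (5.75 in IP and 2.89 in input) and Fosl2 (4.08 in IP and 1.47 in input) rose more in IP, and Hes5 (-3.09 in IP and -0.89 in input) fell more. The count was 202 without CNO replicate 4, 143 without the mouse as a block and 469 by voom on recovered reads.

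In mice with the Gq-coupled receptor hM3Dq CNO changed the astrocyte pull-down more broadly. Reactive genes rose in 9 of 12 cases for the pan-reactive list (10 adjusted over the list alone), such as Cd44 (6.73±0.993 to 104±12.8, 4.00), Osmr (10.5±2.06 to 95.01±13.6, 3.24) and the protease inhibitor Timp1 (3.23±1.06 to 49.5±9.85, 4.02). All 12 genes of the A2 list rose (12 adjusted over the list alone, median 4.20), such as the cytokine Clcf1 (0.218±0.0488 to 43.5±12.3, 7.12), Ptx3 (0.967±0.150 to 64.2±25.4, 5.92) and Emp1 (2.32±0.284 to 106±11.7, 5.52). Of 11 A1 genes 3 rose and 1 fell (3 and 1 adjusted over the list alone). Other steep rises were in the transcription factor Fosl1 (0.0580±0.0527 to 15.2±3.61, 6.67), the TWEAK receptor Tnfrsf12a (1.60±0.874 to 108±26.4, 6.16), Sphk1 (0.250±0.103 to 20.3±7.18, 5.90), thrombomodulin, Thbd (0.160±0.0795 to 14.5±3.13, 5.89), and the cytokine Il11 (0.139±0.0893 to 12.1±2.08, 5.81). Camera gave adjusted p of 1.4e-05 and 1.6e-10 for the pan-reactive and A2 lists, and adjusted p = 0.44 and 0.29 with an estimated correlation.

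Early response, cholesterol biosynthesis and stress genes rose with hM3Dq as well. Of 21 immediate early genes 15 rose (15 adjusted over the list alone), such as Atf3 (1.03±0.527 to 26.7±6.86, 4.69) and Fosl2 (1.74±0.532 to 11.3±0.890, 2.75). Of 21 cAMP and CREB targets 12 rose and 2 fell (12 and 2 adjusted over the list alone), such as Gem (4.20±0.879 to 84.3±15.5, 4.37). Cholesterol biosynthesis rose in 17 of 20 genes (17 adjusted over the list alone), such as Pmvk (37.7±3.14 to 254±38.0, 2.81) and Msmo1 (137±7.64 to 617±36.2, 2.24). The unfolded protein and heat shock response rose in 16 of 18 (17 adjusted over the list alone), such as the chaperone Hspa5 (113±21.9 to 297±7.88, 1.49). Of 16 NF-kappa-B and acute-phase genes 12 rose (13 adjusted over the list alone), such as Socs3 (2.30±1.02 to 78.9±15.5, 5.18), and of 22 interferon response genes 8 (8 adjusted over the list alone), such as Rsad2 (12.3±3.81 to 41.2±11.6, 1.81). By camera the result was adjusted p of 2.2e-05, 0.0059, 3.2e-09, 1.1e-05, 7.8e-05 and 0.015 for these 6 lists, and adjusted p = 0.44, 0.44, 0.44, 0.44, 0.52 and 0.95 with an estimated correlation.

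Genes of astrocyte identity and of extracellular homeostasis fell with hM3Dq. Of 20 astrocyte markers 14 fell and 1 rose (14 and 1 adjusted over the list alone), such as the growth factor receptor Fgfr3 (134±3.93 to 70.4±5.47, -0.86) and the connexin Gja1 (405±17.4 to 229±31.5, -0.76). Of 20 genes of potassium, glutamate and GABA homeostasis 14 fell (15 adjusted over the list alone), such as the glutamine transporter Slc38a3 (136±7.32 to 71.4±10.7, -0.86). Of 9 ependymal markers 7 fell (9 adjusted over the list alone, median -1.10), such as the ciliogenesis factor Foxj1 (57.5±5.74 to 23.9±5.11, -1.21). Of 9 oligodendrocyte precursor markers 5 fell and 1 rose, and of 10 genes of the Sonic hedgehog pathway 7 fell (8 adjusted over the list alone), such as Gli2 (3.36±0.156 to 0.8291±0.235, -1.86). Tested with camera, the result was adjusted p of 5.1e-05, 3.4e-06, 1.2e-04, 0.027 and 0.0012 for these 5 lists, and adjusted p = 0.53, 0.44, 0.44, 0.44 and 0.29 with an estimated correlation. The steepest falls were in Tmem52 (3.96±1.47 to 0.331±0.187, -3.25), Nrarp (26.0±1.34 to 3.03±0.179, -2.99), Hes5 (8.61±2.73 to 1.16±0.323, -2.69), Fam198a (7.05±0.733 to 0.990±0.161, -2.65), Txnip (18.5±6.44 to 3.22±1.35, -2.47), the mitochondrial carrier Ucp3 (7.30±1.18 to 1.19±0.200, -2.45), Sfrp5 (6.70±0.265 to 1.21±0.282, -2.33) and Mettl11b (7.98±1.10 to 1.44±0.245, -2.32). Vehicle replicate 1 carried Y-linked genes at a sum of 16.8 FPKM in IP against 47.1 to 49.8 in the other vehicle mice.

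In input CNO with hM3Dq changed 401 genes upward and 159 downward of 14663 tested. Ptx3 (0.305±0.170 to 7.11±2.42, 4.22), Maff (0.890±0.128 to 15.5±1.54, 3.97), Emp1 (0.914±0.207 to 14.6±1.37, 3.86), Clcf1 (0.608±0.414 to 8.78±2.42, 3.84) and Gem (1.15±0.139 to 18.2±4.59, 3.83) rose most. Ccdc153 (4.50±0.931 to 1.12±0.241, -1.92), Nrarp (7.80±0.354 to 3.24±0.248, -1.25), Hes5 (4.62±0.488 to 2.11±0.614, -1.14), Car4 (4.62±0.791 to 2.17±0.4497, -1.07) and Btbd17 (6.59±0.811 to 3.19±0.537, -1.04) fell most. The effect differed between IP and input for 3271 genes, 1829 more upward and 1442 more downward in IP. Thbd (5.89 in IP and 1.19 in input) and Plaur (5.65 in IP and 1.47 in input) rose more in IP. Txnip (-2.47 in IP and -0.20 in input) and Fam198a (-2.65 in IP and -0.84 in input) fell more.

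The responses to the Gs and the Gq receptor were compared with each other. The CNO effect differed between them for 3904 of 14025 genes, 1687 with the more positive change in rM3Ds and 2217 in hM3Dq (limma, contrast of the changes, adjusted p under 0.05). Klf4 (5.75 with rM3Ds and 1.82 with hM3Dq), Nr4a1 (3.93 with rM3Ds and 1.46 with hM3Dq), Usp2 (1.76 with rM3Ds and -0.73 with hM3Dq), Ppp1r3g (1.93 with rM3Ds and -0.38 with hM3Dq), Fam13c (1.66 with rM3Ds and -0.59 with hM3Dq) and Map3k19 (1.37 with rM3Ds and -1.15 with hM3Dq) changed more upward with rM3Ds, as did the Notch pathway gene Nrarp (0.10 with rM3Ds and -2.99 with hM3Dq) and Fam198a (-0.38 with rM3Ds and -2.65 with hM3Dq). Clcf1 (1.69 with rM3Ds and 7.12 with hM3Dq), Tnfrsf12a (0.90 with rM3Ds and 6.16 with hM3Dq), Angptl4 (-1.76 with rM3Ds and 2.89 with hM3Dq), Tgm1 (0.24 with rM3Ds and 4.88 with hM3Dq), B3gnt5 (0.06 with rM3Ds and 4.69 with hM3Dq) and Plaur (0.89 with rM3Ds and 5.65 with hM3Dq), with Thbd, changed more upward with hM3Dq. Of 606 genes called with rM3Ds among the 13222 tested in both, 428 were called in the same direction with hM3Dq, 41 in the opposite direction and 137 were not called, and 87 of these 137 also differed by the contrast. Members of the A2 list (11 of 12), the pan-reactive list (8 of 12) and cholesterol biosynthesis (12 of 20) changed more upward with hM3Dq, and cAMP and CREB targets (12 of 21) with rM3Ds. Camera gave adjusted p of 1.2e-10, 2.3e-06, 1.3e-06 and 4.8e-04, and adjusted p = 0.32, 0.36, 0.36 and 0.32 with an estimated correlation. The receptors were studied in separate sequencing projects, the hM3Dq time is not labelled, and the rM3Ds arms held 2 females and 2 males each and the hM3Dq arms 4 males each, so receptor, project, time and sex vary together.

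Genes that changed in IP were compared between the experiments. Of the genes called, 31.7% were called in 1 experiment alone with no fold minimum, where independent lists of the same lengths would give 29.8%. At a 2-fold minimum it was 78.5%, where independent lists would give 88.9%. Longer lists overlap more by their length alone, so the difference between these shares is no sign that small changes are shared. With no minimum, of 12933 genes tested in all 6 experiments 11926 were called in at least 1, and 3781 of these in 1 experiment alone. A further 4480 were called in 2 experiments, 2705 in 3, 847 in 4, 113 in 5 and 0 in 6, and of the genes called more than once 2655 changed in the same direction every time and 5490 in opposite directions. How many would share a direction by chance was not computed. Of the 113 genes called in 5 experiments only 2 kept the same direction. Kremen1 was called higher and the histamine receptor Hrh1 lower in 5 experiments, with changes for Kremen1 of 0.37 after QA, 0.68 after LPS, 0.16 with Kcnj10 deletion, 0.61 with rM3Ds and 0.91 with hM3Dq. Maff, Socs3, Ptx3, Ccl2, Ccl7, Fosl1 and Emp1 rose in 4 experiments (QA, LPS, rM3Ds and hM3Dq) and fell with Kcnj10 deletion. With rM3Ds the call of Emp1 was lost without vehicle replicate 3 or CNO replicate 4. Hes5 fell in the same 4 experiments, by 2.15, 4.28, 3.09 and 2.69 on the log2 scale. Across genes, which are not independent replicates, the Pearson correlation of log2 changes was 0.50 between LPS and hM3Dq, 0.48 between rM3Ds and hM3Dq, 0.38 between QA and LPS, -0.44 between LPS and Kcnj10 deletion and -0.53 between QA and Kcnj10 deletion, of 15 pairs computed. Genes higher after QA and lower with Kcnj10 deletion numbered 1471, where independent lists would share 691. Each experiment was sequenced as its own project with its own controls, so experiment and project cannot be separated.

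**Figure D2:**
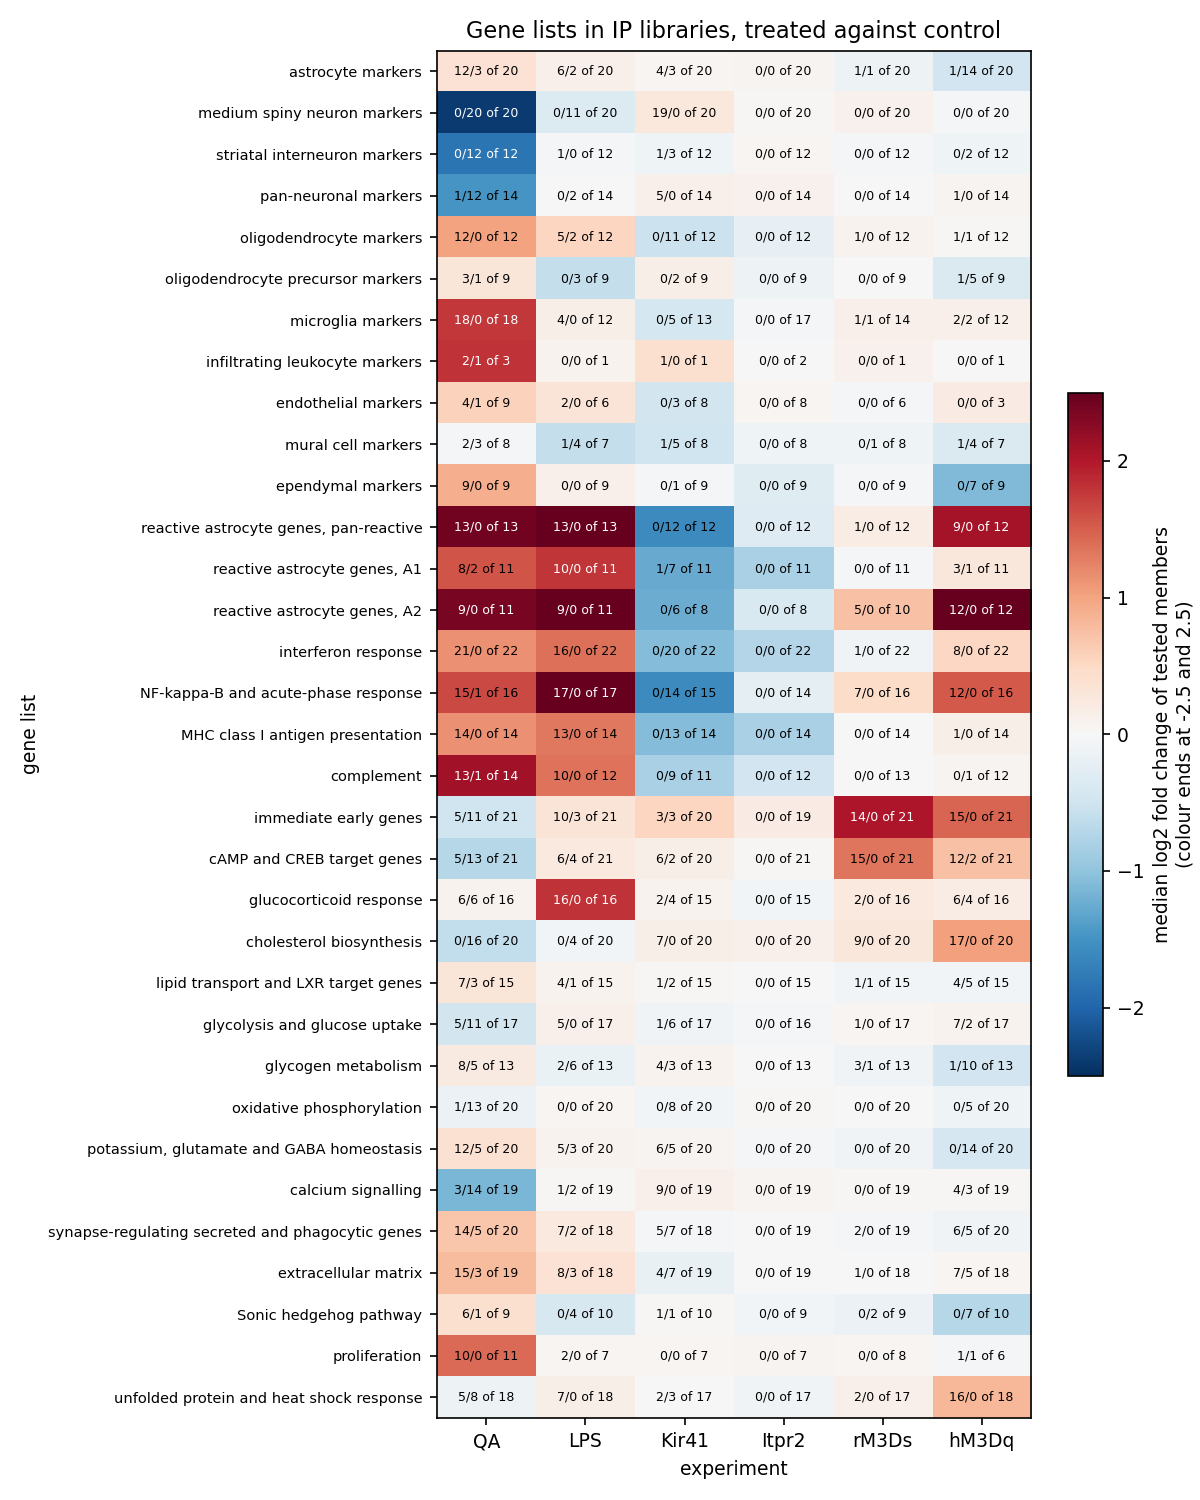
Genes of each fixed list (lines) in IP of each experiment (columns), with the number higher and lower of those tested printed in each cell and the median log2 change as colour. The pan-reactive and A2 lists change upward after QA, LPS and hM3Dq. Both lists are lower with Cre than with TdTomato in the Kcnj10 experiment, where 12 of 12 pan-reactive genes were lower. With rM3Ds 5 of 10 A2 genes and 1 of 12 pan-reactive genes rose. Neither list was called by camera with an estimated correlation.

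**Figure D3:**
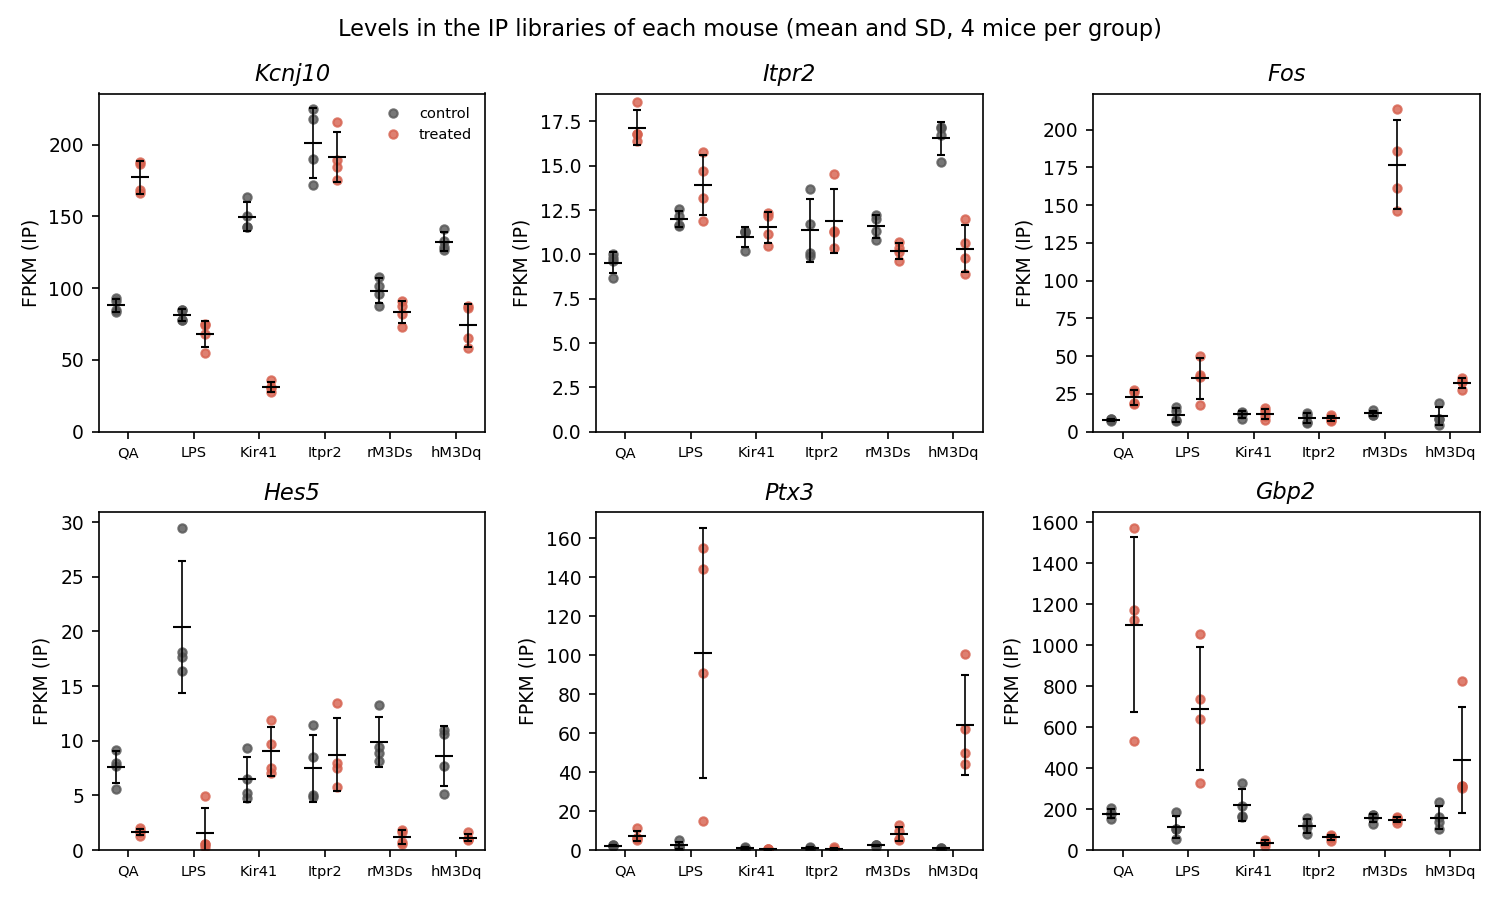
FPKM in IP of Kcnj10, Itpr2, Fos, Hes5, Ptx3 and Gbp2, 1 point per mouse, for control and treated mice of each experiment. Kcnj10 is at 150 ± 10.1 with TdTomato and 31.4 ± 3.45 with Cre, and Itpr2 is at 11.4 ± 1.77 in wild type and 11.9 ± 1.82 in libraries labelled knockout.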

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

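The first search below followed a rule fixed before the data were examined: in each group of 4 libraries, the gap from the highest or lowest library to its nearest neighbour was divided by the range of the group, and values above Dixon's critical value are listed. Chance marks about 1 in 20 groups. Of 72 library measures 5 were marked where chance gives 3.6, of 96 check gene measures 6 where chance gives 4.8, and of 164 named gene measures 15 where chance gives 8.2.

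Among library measures, knockout-label replicate 1 of the Itpr2 experiment had the fewest reads in its IP group (45251106, ratio 0.835). In IP of the hM3Dq vehicle group, replicate 1 had the lowest share of reads in its top 10 genes (8.56%, ratio 0.831) and the highest share of single reads among genes with 1 to 5 reads (22.9%, ratio 0.8998). The same share was lowest in TdTomato input replicate 4 (15.8%, ratio 0.881) and highest in TdTomato IP replicate 2 (34.997%, ratio 0.916).

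Among check genes, Kcnj10 was low in QA vehicle input replicate 2 (9.70 FPKM, ratio 0.897) and high in LPS vehicle input replicate 4 (11.3 FPKM, ratio 0.831). Itpr2 was low in TdTomato IP replicate 1 (10.2 FPKM, ratio 0.952). Rpl22 was low in TdTomato input replicate 2 (68.8 FPKM, ratio 0.835) and in rM3Ds CNO IP replicate 4 (197 FPKM, ratio 0.851). Chrm3 was high in knockout-label IP replicate 3 (7.66 FPKM, ratio 0.975).

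Of the named genes, 7 were marked in LPS IP replicate 2, each higher than in the other LPS mice: Hes5 (4.98 FPKM, ratio 0.947), Gpr17 (4.68, ratio 0.966), Nrarp (14.4, ratio 0.973), Ak4 (5.78, ratio 0.831), Shisa2 (1.92, ratio 0.850), Fam13c (9.44, ratio 0.932) and Kctd21 (5.22, ratio 0.889). These genes fell after LPS, and this mouse lay nearest the vehicle mice. Hes5 was also high in LPS vehicle IP replicate 2 (29.4 FPKM, ratio 0.866). QA vehicle IP replicate 1 was high in Igfbp2 (36.4 FPKM, ratio 0.847) and Rgs4 (255 FPKM, ratio 0.884), and Cre IP replicate 2 in Ccl2 (2.34 FPKM, ratio 0.896) and Cxcl10 (15.4 FPKM, ratio 0.841). Txnip was high in rM3Ds vehicle IP replicate 4 (23.4 FPKM, ratio 0.835), Ucp3 was high in hM3Dq CNO IP replicate 3 (1.49 FPKM, ratio 0.931), and Mettl11b was low in hM3Dq vehicle IP replicate 4 (6.33 FPKM, ratio 0.892).

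A second search listed treatment effects that differed between IP and input by a limma interaction. They differed for 7187 genes after QA, 1308 after LPS, 359 with Kcnj10 deletion, 306 with rM3Ds and 3271 with hM3Dq, and for 3904 genes the CNO effect differed between rM3Ds and hM3Dq.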

How the results depend on the processing

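Deposited scaling, the pseudocounts, voom on recovered reads, female mice alone and the other split as a covariate were chosen after seeing the data. Of 408 alternative values 326 stayed within 1.5 times the reported count, or within its spread, and 82 moved, 53 of them among 214 that leave out a library or mouse. All 27 values with RLE scaling stayed, as did 20 with a pseudocount of 1 and 12 with 0.01. No named gene reversed under any alternative. Calls kept were counted over RLE scaling, the replicate block, deposited scaling, voom and leaving out a library. There they were at fewest 142 of 147 for QA, 83 of 108 for LPS, 112 of 120 for Kcnj10 deletion, 33 of 43 for rM3Ds and 102 of 107 for hM3Dq. The other alternatives are outside this count. With the spread over all 48 libraries further named genes of Kcnj10 deletion lost their call, such as Mbp (limma adjusted p = 0.069) and Syt1 (limma adjusted p = 0.23). With an estimated correlation the lists called in IP were 0 for QA, LPS, Kcnj10 deletion, Itpr2 and hM3Dq and 2 for rM3Ds. With the spread over all 48 libraries the counts were 1631 and 29 in IP of the Kcnj10 and Itpr2 experiments and 160 and 5 in their input. With the other split as a covariate rM3Ds IP gave 960 and Itpr2 input 0. With no filter Kcnj10 input gave 16 and Itpr2 input 0, with sex as a covariate 31 and 0, and with voom on recovered reads 139 and 0. Voom gave 694 and 469 interaction genes for Kcnj10 deletion and rM3Ds. The share of called genes in 1 experiment only was 41.7% with no filter, 78.5% at a 2-fold minimum and 29.0% with deposited scaling. A 2-fold minimum leaves fewer genes, and for the other shifts the cause was not tested.

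Replicate numbers did not pair the mice: 0 of 12 comparisons had a correlation above 0.1 in all 4 pairs, and 9 of 48 pairs did. With the replicate as a block the counts were 28 for Kcnj10 input, 0 for Itpr2 input and 342 for hM3Dq input, and the share in 1 experiment only was 36.1%. Without the mouse as a block the interaction counts were 168 for LPS and 143 for rM3Ds. The cause was not tested.

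Leaving out 1 library, or both libraries of a mouse, gave these lowest and highest counts: in IP 2155 (without LPS replicate 3) to 8256 (without LPS replicate 2) for LPS, 0 to 9 for Itpr2 (9 without wild-type replicate 3) and 413 (without CNO replicate 4) to 589 (without vehicle replicate 4) for rM3Ds. Itpr2 lists ran from 8 (without wild-type replicate 2) to 16 (without wild-type replicate 3). In input the ranges were 1757 to 8623 for LPS, 1 to 86 for Kcnj10 deletion and 0 to 3 for Itpr2. For the interaction they were 296 to 4823 for LPS, 127 to 404 (without Cre replicate 4) for Kcnj10 deletion, 0 to 1 for Itpr2 and 202 to 294 (without vehicle replicate 1) for rM3Ds. With 4 mice per arm, changes of 1.5-fold were recovered in 40.3% of simulated LPS IP genes, so small changes can be missed.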

Other observations

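Some metabolic and structural lists outside the main comparisons were called by camera. Oxidative phosphorylation genes fell in 13 of 20 cases and rose in 1 after QA, and fell in 8 of 20 with Kcnj10 deletion, such as Cox7c (9.39±0.883 to 6.74±0.641, -0.43), and in 5 of 20 with hM3Dq. With hM3Dq 10 of 13 glycogen genes fell and 1 rose, such as Ugp2 (101±7.49 to 54.8±8.11, -0.82). Camera gave adjusted p of 0.030, 0.0016, 0.015 and 0.0018 in that order, and adjusted p = 0.49, 0.50, 0.71 and 0.44 with an estimated correlation. Matrix and synapse-regulating genes rose after QA in 15 of 19 and 14 of 20 cases and fell in 3 and 5, for example the laminin Lamb2 (12.3±0.480 to 27.0±1.40, 1.08) and thrombospondin-2, Thbs2 (1.86±0.238 to 8.72±0.507, 2.13) (camera adjusted p = 7.7e-04 and 0.0099, and adjusted p = 0.44 and 0.36 with an estimated correlation). After QA calcium signalling genes fell in 14 of 19 cases and rose in 3, and pan-neuronal markers fell in 12 of 14 and rose in 1. Potassium, glutamate and GABA homeostasis genes rose in 12 of 20 and fell in 5. After LPS synapse-regulating genes rose in 7 of 18 and fell in 2. Camera adjusted p was 0.0040, 0.0019, 0.028 and 0.048 in that order, and 0.51, 0.49, 0.49 and 0.31 with an estimated correlation. QA changed 10238 of 13824 genes in all, so many changed members are no sign of a list that moved.

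Other lists had changed members and did not pass as lists by camera. After QA 11 of 17 glycolysis genes fell and 5 rose, with Hk2 (0.758±0.143 to 3.10±0.533, 1.86) and Ldha (93.5±2.94 to 59.9±5.34, -0.69) as opposite examples (adjusted p = 0.51), and 8 of 13 glycogen genes rose and 5 fell (adjusted p = 0.37). Lipid transport genes rose in 7 of 15 cases and fell in 3, such as Apod (380.4±58.0 to 2817±1236, 2.77) (adjusted p = 0.23), Hedgehog pathway genes rose in 6 of 9 and fell in 1, such as Gli2 (1.32±0.0984 to 3.23±0.534, 1.18) (adjusted p = 0.058), and of 18 unfolded protein genes 5 rose and 8 fell (adjusted p = 0.56). After LPS 6 of 13 glycogen genes fell and 2 rose (adjusted p = 0.16), 8 of 18 matrix genes rose and 3 fell, such as the collagen Col4a1 (3.01±0.284 to 15.7±6.59, 2.34) (adjusted p = 0.10), 4 of 10 Hedgehog genes fell (adjusted p = 0.099) and 7 of 18 unfolded protein genes rose, such as Hspa5 (124±5.30 to 191±25.5, 0.75) (adjusted p = 0.067). With Kcnj10 deletion 4 of 19 matrix genes rose and 7 fell, such as the metalloproteinase Mmp2 (9.42±0.441 to 4.20±0.566, -1.12) (adjusted p = 0.15), and with hM3Dq 7 of 17 glycolysis genes rose and 2 fell, such as Hk2 (0.698±0.216 to 9.28±2.92, 3.62) (adjusted p = 0.14).

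The tests of the interneuron markers, of the Kcnj10 deletion pattern, and of sex and single libraries in the rM3Ds mice were chosen only after the result was seen. Gene length was chosen before. The counts over other splits followed a rule fixed before the data were examined but were written down afterwards. Striatal interneuron markers were higher in IP than in input. RNA carried over from the tissue would leave a ratio at or below 1, and the median log2 ratio was 1.75. Scaling of the libraries as the whole cause is argued against by the lowest median over 3 scalings, 1.52. Tagged ribosomes in some interneurons may be a source: the markers changed by a median of -1.83 after QA, which medium spiny neuron markers also did (-2.39), so these cannot be told apart from the general neuronal loss.

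Reactive, interferon and antigen presentation genes were lower in Cre than in TdTomato IP, 77 of 88 genes in 7 lists. Carried-over RNA adds at most its share of the input value to IP, which limits the fall that its loss can give. Of the 88 genes 77 were higher in IP than in input of control mice. Microglia markers stood in TdTomato IP at a median of 0.030 of their input value, with an upper quartile of 0.093. At this upper quartile the loss of microglial RNA would allow a median log2 change of -0.05, and the change of the 77 genes minus this limit had a median of -1.14, with 74 of them beyond the limit, which argues against less RNA from microglia. With carry-over at the whole input value, the upper limit for any cells, the median difference from the limit was -0.498 and 57 of 77 genes passed it. The upper quartile did not (0.13), so a part from other cells cannot be told apart from a change in astrocytes. For the 11 genes not higher in IP than in input, such as C1qa, the limit was never passed (median difference 3.598), and less carry-over stays open. The genes also fell in input (median -0.74), which less carry-over would leave unchanged, but input libraries with few single-read genes go along with the Cre arm. A raised level in the TdTomato controls cannot be told apart from a lowered level with Cre: 1 of the control groups of the other 5 experiments had a lower mean (TdTomato 3.48, other controls 3.03 to 3.88, Cre 2.22 on the log2 scale), and each experiment is its own project. The biological reading, that loss of Kcnj10 lowers these genes, stays open.

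The split of the rM3Ds mice that called 2185 genes in IP and 1002 in input points to a structure of these samples. A comparison of females with males, for sex of the mice, called 6 genes, removing each library's trend over gene length left 2080, and 100% of the 582 genes that the split called in both IP and input differed in the same direction, which argues against a fault of single libraries. Along this split, which was picked because it called the most genes, camera called 4 of 32 lists in IP. Interferon response genes were lower (adjusted p = 0.0021) and ependymal, mural and pan-reactive genes higher (adjusted p = 0.014, 0.022 and 0.022) in vehicle replicates 1 and 4 and CNO replicates 3 and 4 than in the rest, each with adjusted p = 0.81 by an estimated correlation. In input camera called 0 of 33 lists (7 at an unadjusted p under 0.05), and 0 with an estimated correlation. Mice that were handled together may be a source, but the labels give no batch, and apart from sex no biological explanation was tested.

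Other splits of the same mice were counted for each result, the real split included. The splits argue against chance in IP for QA (10238 genes, highest other split 0), LPS (5016, highest other 1), Kcnj10 deletion (3999, highest other 2) and hM3Dq (6224, highest other 2), each with 1 of 35 splits as large. They do so in input for QA (10918, highest other 1), LPS (4502, highest other 2), Kcnj10 deletion (49, highest other 4) and hM3Dq (560, highest other 3), each with 1 of 35. They also do so for the interactions of QA (7187, highest other 0), LPS (1308, highest other 0), Kcnj10 deletion (359, highest other 1), rM3Ds (306, highest other 1) and hM3Dq (3271, highest other 1), each with 1 of 35, and for IP against input (6843, highest other 5730, 1 of 100 splits). These shares are the smallest that so few splits can give, and many results were tested, so chance is not excluded. The Kcnj10 input count fell to that of the highest other split or below when single TdTomato mice were left out. In the QA experiment the arms nearly follow sex.

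Chance cannot be excluded for the remaining counts. With rM3Ds 2 of 35 splits were as large in IP (620, highest other 2185) and in input (86, highest other 1002). With Itpr2 the splits as large were 35 of 35 in IP (0, highest other 2), 10 of 35 in input (1, highest other 92) and 35 of 35 for the interaction (0, highest other 1), where limma called 0 genes, 788 and 716 had an unadjusted p under 0.05 in IP and the interaction, and voom called 0. Every split matches a count of 0, so 35 of 35 was fixed in advance and decides nothing. For rM3Ds against hM3Dq the splits as large were 5 of 100 (3904, highest other 4998). For the number of lists called by camera at the preset correlation they were 4 of 35 for QA (21, highest other 23), 16 for LPS (11, highest other 17), 9 for Kcnj10 deletion (15, highest other 22), 5 for Itpr2 (13, highest other 16), 8 for rM3Ds (11, highest other 16) and 9 for hM3Dq (15, highest other 18). At the preset correlation arbitrary splits of these mice thus called as many lists, and the list results describe their members without excluding chance.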
